A study of Homo sapiens with 16 samples.

How the data were processed

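RNA from 4 mantle cell lymphoma lines was measured on 16 Affymetrix human expression arrays. Per the labels, cells in 3 ml of medium received 0.025% DMSO or 2.5 µM sotrastaurin (AEB071, an inhibitor of protein kinase C) for 3 h. Jeko-1 and Mino are labelled sensitive to the drug and were grown with 20% serum, and Z-138 and Maver-1 are labelled insensitive and were grown with 10% serum, so serum content and class coincide. RNA was extracted with RNeasy Plus, amplified with the NuGEN Ovation chemistry and labelled with biotin, and each of the 8 groups (line by agent) has 2 arrays. Nothing in the labels says that the replicates were separate cultures, so every p-value measures only the spread between these samples.

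The deposited values are intensity values, linear signals that were made by the authors with MAS5, per the submitters' processing notes, which state no version. The mean of each array without the lowest and highest 2% of its values was about 150.0 in all 16 arrays, so the arrays had been scaled to 1 level before deposit, and they were not scaled again. The number of arrays, 2 per group, limits the precision of each value. Of 54675 probe sets, 41091 carried 1 gene symbol, 1801 carried several, 11721 carried none, and 62 were controls. The probe table gave an Entrez identifier found in the reference gene table for 41037 of the probe sets with 1 symbol, and 0 symbols were changed by it. No genome build is named in the files, so no coordinates are printed.

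Signals were changed to log2 after adding 16. A probe set with 1 symbol was kept when the highest of its 8 group means lay above the median of all values, log2 4.853 or a signal of 12.9. The kept probe set with the highest mean stood for its gene, which left 12722 genes. Effects of sotrastaurin were tested in R 4.3.3 with limma 3.58.1 (lmFit, and eBayes with an intensity trend) in a single fit of all 16 arrays with a mean for each of the 8 groups. The fit had 8 residual degrees of freedom, and the trend prior added 7.90. All tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The contrasts were the mean change over Jeko-1 and Mino, the mean change over Z-138 and Maver-1, the difference between these means, and the change in each line. For the class difference under DMSO the arrays of a line were averaged before a limma test of 2 lines against 2. Errors beside log2 changes are standard errors from limma, and errors beside signals are standard deviations over the 2 arrays of a group.

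The comparisons, the tests, 29 gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 27 lists with at least 3 measured genes in a comparison. Camera with an estimated correlation, and fry, were run beside it. Genes were named as follows. For the sensitive and insensitive effects, these were the 12 largest rises and 12 largest falls past the threshold whose sotrastaurin arrays lay on the same side of the DMSO arrays in both lines of the class. For the difference, they were the 12 largest in each direction, for each line the 5 largest in each direction without overlap of the arrays, and for the DMSO comparison the 10 genes with the smallest p. Up to 4 members of each list with the smallest p, and a fixed set of always-named genes, completed the names. Genes that the probe table does not give under a single symbol, and some others, are not reported here.

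Alternatives covered the pseudocount, the filter, quantile normalization and median centring, the choice of probe set, the variance trend, a minimum change, the arrays in the fit, a replicate block, lines in place of arrays as replicates, and leaving out each array in turn. Added after the values were seen were a filter at a signal of 100, array weights estimated by limma, lists without Jeko-1 DMSO replicate 1, tests of the lists between the lines of a class, lists for the class difference over genes with a signal above 100 in both insensitive lines under DMSO, and the class difference over the sotrastaurin arrays. When 1 array of a group was left out, the lone array was assumed to vary like the other groups. The fit was tested on simulated data with known changes: at a log2 change of 1, 100% of the changed genes were recovered for the sensitive lines and 94.0% for the difference between classes. At a log2 change of 0.5 these shares were 70.1% and 37.3%, with 79.1% for the insensitive lines and 34.3% to 49.3% in single lines, so changes of that size can be missed. For the DMSO comparison 0% were recovered at a log2 change of 2, and 6.06% at 4. There the spread between lines was taken from all 4 lines around 1 mean, class differences included. For the effects of sotrastaurin the simulation gave a gene the same spread in all 8 groups. It therefore does not show the false calls or losses that a wider spread in 1 group, as in Jeko-1 DMSO, can give.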

Results

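Expression was measured on 16 arrays from 4 mantle cell lymphoma lines, each treated for 3 h with DMSO at 0.025% or with sotrastaurin at 2.5 µM, with 2 arrays per group. Mantle cell lymphoma is a B-cell tumour driven by cyclin D1, and sotrastaurin inhibits protein kinase C, which relays signals from the B-cell receptor to the transcription factor NF-kB. Jeko-1 and Mino were labelled sensitive to the drug, and Z-138 and Maver-1 insensitive. The study compares the transcriptional response to inhibition of protein kinase C between these classes. Under DMSO CCND1 and SOX11 were expressed in all 4 lines. CCND1, which encodes cyclin D1, had a mean signal of 2119 ± 157 in Jeko-1, 625 ± 98.7 in Mino, 2144 ± 8.49 in Z-138 and 1181 ± 27.2 in Maver-1 (SD, n = 2), and SOX11, a transcription factor of this tumour, lay between 1373 ± 58.2 in Maver-1 and 2232 ± 146 in Z-138. The median signal of an array was near 13.1, and 12722 genes passed the filter on low values. Of 65 marker genes of T and NK, myeloid, stromal and erythroid cells, 15 passed that filter.

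Jeko-1 DMSO replicate 1 stood apart from the other 15 arrays. Its ratio of the 5′ to the 3′ ACTB probe set was 0.238, against 0.365 to 0.550 in the others, and its lys control signal was 48.8 against 10.0 to 19.9. Its 5′ to 3′ ratio for GAPDH, 0.743, lay inside the range of the others. The standard deviation of the log2 difference between the Jeko-1 DMSO arrays was 0.325, against 0.178 to 0.226 for the other 7 pairs. Without this array the lists tested with camera also changed in places, and those values are given with the counts of each comparison.

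In the sensitive lines sotrastaurin lowered NF-kB target genes. BCL2A1, which encodes an antiapoptotic member of the BCL2 family, fell most, with a log2 change of -2.09 ± 0.09 (SE, 4 arrays against 4, limma adjusted p = 1.4e-09). Its signal went from 133 ± 14.8 to 36.9 ± 3.39 in Jeko-1 and from 2076 ± 107 to 309 ± 4.88 in Mino (SD, n = 2). TNFAIP3, which encodes the deubiquitinase A20, fell by 1.49 ± 0.07 (adjusted p = 2.1e-09), NFKBID fell by 1.83 ± 0.11 (1.4e-08) and NFKBIA, which encodes the inhibitor IkB-alpha, fell by 1.22 ± 0.11 (6.8e-06). Other falls were those of the chemokine CCL4 (-1.77 ± 0.09), the adhesion molecule ICAM1 (-1.77 ± 0.10), CD83 (-1.55 ± 0.08), the costimulatory receptor CD40 (-1.26 ± 0.12) and BCL2L1 (-1.14 ± 0.11), which encodes the survival protein BCL-XL. The fall of BCL2L1 rested on Mino (-2.12), with -0.15 in Jeko-1 (adjusted p = 0.59). Each of these calls held with any 1 of the 16 arrays left out.

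Of the 44 measured genes in the list of NF-kB targets, 27 fell, 0 rose and 17 did not pass the test, and adjusted over the list alone 33 fell and 1 rose. The list's mean log2 change was -0.66, with 40 of 44 fitted changes below 0 (camera adjusted p = 3.9e-38, and adjusted p = 1.4e-04 with an estimated correlation). In the list of chemokines and cytokines 5 of 16 fell and 0 rose, 6 and 0 adjusted over the list alone, with a mean of -0.35 (adjusted p = 3.3e-06, and 0.0081 with an estimated correlation). By line this list passed in Mino, at -0.48 with 5 falls (1.6e-09, and 0.0017 with an estimated correlation), and not in Jeko-1, at -0.21 with 2 falls (0.25, or 0.055 with 1 fall without Jeko-1 DMSO replicate 1). The difference, Mino minus Jeko-1, was -0.27 (0.0025, and 0.030 with an estimated correlation). The falls included CCL4, IL21R (-0.85 ± 0.10), IL2RA (-0.56 ± 0.09) and TNF (-0.54 ± 0.09), and 10 of the 16 also stand in the NF-kB list. IL2RA and TNF fell in Mino (-1.05 and -1.14) and not in Jeko-1 (-0.08 and 0.07), and IL21R did not pass in Jeko-1 (-0.41, 0.077). Of 14 components of the alternative NF-kB pathway, which runs through MAP3K14 and not through protein kinase C, CD40 and RELB (-0.64 ± 0.09, adjusted p = 5.3e-04) fell and TNFRSF13B rose (0.48 ± 0.12, adjusted p = 0.044, lost without several single arrays, at most 0.19 without Mino sotrastaurin replicate 1). MAP3K14 itself was at -0.25 ± 0.15 (0.37), TRAF3 at -0.07 ± 0.14 (0.83) and NFKB2 at -0.42 ± 0.12 (0.071). The list did not pass (adjusted p = 0.072). CD40 and RELB also stand in the NF-kB list. Without the 3 members shared with that list, the other 11 had 1 rise, 0 falls and a mean of -0.00041. The transcript of PRKCB, a protein kinase C isoform of B-cell receptor signalling, was at -0.04 ± 0.07 (0.78), and that of MALT1, which acts downstream of it, at -0.02 ± 0.07 (0.92).

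Among the largest rises in the sensitive lines were those of TSC22D3, which encodes the glucocorticoid-induced leucine zipper protein (1.77 ± 0.08, a 3.41-fold rise, adjusted p = 1.7e-09), and the Krüppel-like factors KLF6 (1.14 ± 0.08, 1.1e-07), KLF2 (0.91 ± 0.08, 6.8e-06) and KLF7 (0.84 ± 0.07, 1.6e-06). The growth factor transcript HBEGF rose by 0.89 ± 0.08 (9.1e-06). In the list of FOXO target genes 5 of 23 rose and 0 fell, 6 and 0 adjusted over the list alone, with a mean of 0.29 (camera adjusted p = 6.0e-08, adjusted p = 0.060 with an estimated correlation). Its difference between the lines, Mino minus Jeko-1, was -0.13 (0.046, and 0.50 with an estimated correlation). The rises included TSC22D3, KLF6, KLF2 and TXNIP (0.43 ± 0.10). The call of TXNIP was lost without several single arrays, with an adjusted p of at most 0.082 without Mino sotrastaurin replicate 2.

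Immediate-early genes went both ways. Of 30 measured, 4 rose and 13 fell, 6 and 15 adjusted over the list alone, with a mean of -0.17 (adjusted p = 0.0046, and 0.060 with an estimated correlation). Among the falls were the transcription factors EGR3 (-1.55 ± 0.09, 1.4e-08), NR4A3 (-1.15 ± 0.11, 8.9e-06) and EGR1 (-0.61 ± 0.11, 0.0052), and among the rises were KLF6, KLF2 and HBEGF. MYC was at 0.51 ± 0.14 (0.062). The mean rested on Mino, where the list was at -0.34 (adjusted p = 1.6e-08, and 0.0027 with an estimated correlation), against -0.01 in Jeko-1 with 5 rises and 5 falls (0.88), a difference of -0.33 (2.1e-05, and 0.012 with an estimated correlation). In Jeko-1 EGR3 was at -0.39 (0.072) and EGR1 at -0.09 (0.77). The MEK-ERK list, which includes the phosphatase DUSP5 (-0.73 ± 0.12, 0.0032) and IER3 (-0.59 ± 0.09, 0.0010) among its 4 falls of 19, did not pass as a group over both lines (0.060, or 0.038 with median centring). In Mino alone it had a mean of -0.21 with 4 falls and passed (0.0019, and 0.049 with an estimated correlation, or 0.062 without Jeko-1 DMSO replicate 1). In Jeko-1 it was at -0.06 with 1 rise and 0 falls (0.72), and the difference between these lines, -0.15, did not pass (0.093). In the list of unfolded protein and amino acid stress genes 7 of 25 fell and 1 rose, 12 and 1 adjusted over the list alone, with a mean of -0.17 (adjusted p = 1.7e-04, and 0.060 with an estimated correlation). Its falls included HERPUD1 (-0.46 ± 0.06), the cystine transporter SLC7A11 (-0.45 ± 0.07) and ATF3 (-0.50 ± 0.08). Of the BCL2 family and apoptosis list 5 of 26 fell and 1 rose, 8 and 3 adjusted over the list alone, with a mean of -0.20 (adjusted p = 0.010, and 0.060 with an estimated correlation). The fall of this list was in Mino, at -0.36 with 5 falls (6.6e-07, and 0.0027 with an estimated correlation), against -0.04 in Jeko-1 with 1 fall (0.86). The difference between these lines was -0.32 with 5 members lower (9.9e-05, and 0.012 with an estimated correlation). BCL2A1, BCL2L1, the death receptor FAS (-0.80 ± 0.09) and CFLAR (-0.69 ± 0.10) fell, although FAS was near the floor in Jeko-1 (0.27) and its fall rested on Mino (-1.87 ± 0.13), as did that of CFLAR (-1.18 in Mino and -0.19 in Jeko-1). Without the 4 members that also stand in the NF-kB list its mean was -0.02. The B-cell receptor pathway components (26 measured, 0 past the threshold) had a mean of -0.07 (0.29). Over both lines the cell-cycle lists did not pass (0.66 for 28 G1-S genes, 0.38 for 28 G2-M genes), but the G2-M genes moved apart by line. In Mino their mean was 0.12, with 23 of 28 fitted changes above 0 and 0 past the threshold (0.0025, and 0.037 with an estimated correlation, or 0.062 without Jeko-1 DMSO replicate 1). In Jeko-1 it was -0.08 with 3 falls (0.55). The difference, Mino minus Jeko-1, was 0.20 (0.012, and 0.066 with an estimated correlation, or 0.023 without Jeko-1 DMSO replicate 1).

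**Figure D1:**
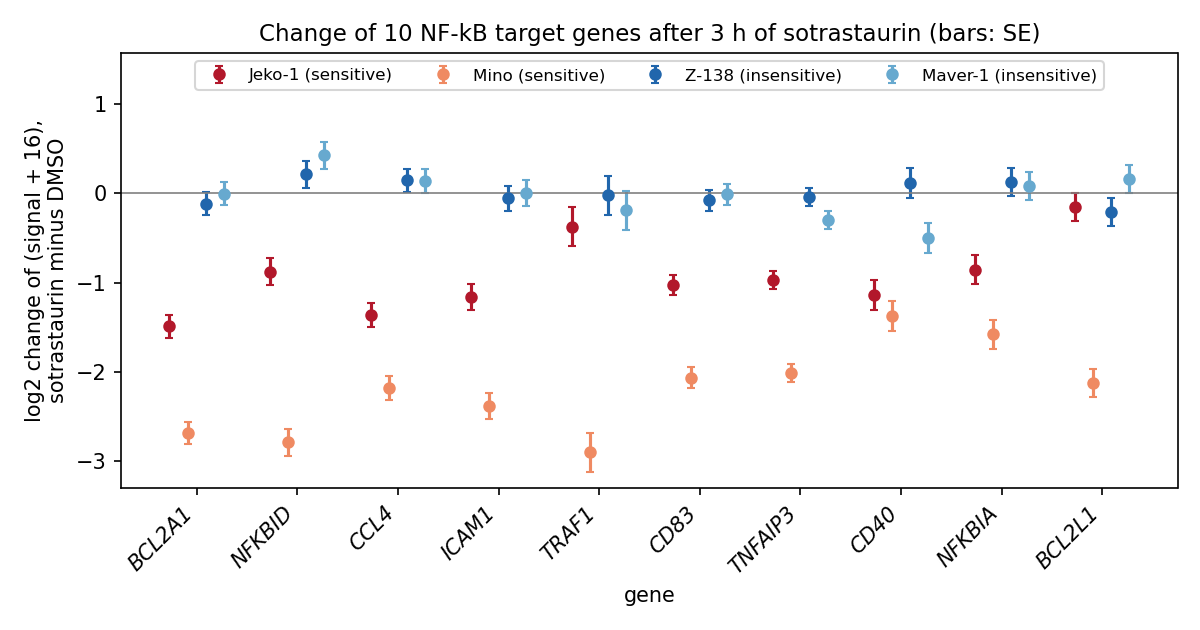
The plot gives the log2 change (sotrastaurin against DMSO, ± SE from limma, n = 2 arrays per group) of 10 NF-kB genes in each of the 4 lines. BCL2A1 lay at -1.49 in Jeko-1 and -2.68 in Mino, and at -0.12 in Z-138 and 0.00 in Maver-1.

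Over the sensitive lines 356 of 12722 genes passed the limma threshold, 153 higher and 203 lower, and 19 of them changed by at least 1 on the log2 scale. The count depends on single arrays: it was 225 without Jeko-1 DMSO replicate 1, 2593 without Jeko-1 DMSO replicate 2, 139 without Jeko-1 sotrastaurin replicate 1, 179 and 176 without Mino DMSO replicates 1 and 2, and 157 and 219 without Mino sotrastaurin replicates 1 and 2. Without Jeko-1 DMSO replicate 1 the NF-kB list still had 27 falls and a mean of -0.64, the unfolded protein list had 5 falls, and the estimated-correlation adjusted p was 0.025 for the FOXO and unfolded protein lists and 0.048 for the immediate-early and BCL2 family lists. The preset-correlation adjusted p went from 0.060 to 0.0067 for the MEK-ERK list (0.084 with an estimated correlation), from 0.093 to 0.017 for JAK-STAT target genes (0.074) and from 0.076 to 0.032 for cholesterol synthesis genes (0.089), so none of the 3 passed over both lines with an estimated correlation. By line, the JAK-STAT genes passed in Mino, with a mean of -0.33 and 3 falls of 17, PIM1, IL21R and IL2RA (2.9e-06, and 0.0055 with an estimated correlation). In Jeko-1 they had a mean of 0.10 (0.47), and the difference, Mino minus Jeko-1, was -0.43 (2.1e-05, and 0.012 with an estimated correlation). Without the 2 members that also stand in the NF-kB list, of which IL2RA is 1, the JAK-STAT mean over both lines was -0.12. That mean was not computed for Mino alone, so it cannot be set against the -0.33 there. With lines as the replicates limma called 14 genes, and with only the 8 arrays compared in the fit 120.

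In the insensitive lines sotrastaurin raised TSC22D3, as in the sensitive lines, and the list of NF-kB target genes did not pass the test. TSC22D3 rose by 1.61 ± 0.08 (SE, 4 arrays against 4, limma adjusted p = 1.5e-08, 3.04-fold), from 249 ± 6.65 to 727 ± 85.6 in Z-138 and from 391 ± 53.5 to 1325 ± 18.4 in Maver-1. KLF2 rose by 0.75 ± 0.08 (2.4e-04), KLF6 by 0.63 ± 0.08 (6.3e-04) and ZFP36, which encodes an RNA-binding protein that destabilises cytokine transcripts, by 0.65 ± 0.09 (0.0028). By line, KLF2, KLF6 and ZFP36 passed in Maver-1 (1.13, 0.75 and 0.96) and not in Z-138 (0.37, 0.50 and 0.33), but none of the 3 passed a test of the difference between these lines (0.49, 0.99 and 0.99). The B-cell transcription factor SPIB rose by 0.64 ± 0.08 (6.3e-04) and SPSB1 by 0.84 ± 0.10 (3.2e-04). The largest falls were of RGS1 (-1.13 ± 0.09, 4.5e-06) and RGS2 (-0.80 ± 0.08, 1.5e-04), which encode regulators of G-protein signalling, and of the ubiquitin ligase gene RNF144B (-0.76 ± 0.08, 9.5e-05). Each of these calls held with any 1 array left out.

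Of the 44 NF-kB targets 0 rose and 0 fell, 1 and 1 adjusted over the list alone, with a mean of 0.01 (limma and camera, adjusted p = 0.92, with 823 of all genes at an unadjusted p under 0.05). These genes were not all silent there. TNFAIP3 had a signal of 648 ± 17.3 under DMSO and 630 ± 0.99 under sotrastaurin in Z-138, and 377 ± 11.1 and 304 ± 4.81 in Maver-1, a mean log2 change of -0.17 ± 0.07 (0.66). NFKBIA was at 394 ± 1.91 and 431 ± 1.27 in Z-138 and at 320 ± 1.2 and 340 ± 37.2 in Maver-1 (0.10 ± 0.11, adjusted p = 0.97). BCL2A1 was near the floor, with 2.90 ± 1.41 in Z-138 and 8.0 ± 1.41 in Maver-1 under DMSO.

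Of 30 immediate-early genes in the insensitive lines, 5 rose and 2 fell, 8 and 3 adjusted over the list alone, with a mean of 0.10 (camera adjusted p = 8.5e-04, and 0.035 with an estimated correlation). By line, Maver-1 had a mean of 0.17 and 4 rises (3.5e-06, and 0.025 with an estimated correlation, or 0.068 without Jeko-1 DMSO replicate 1), whereas Z-138 had a mean of 0.02 with 0 rises and 2 falls (0.58). The difference, Z-138 minus Maver-1, was -0.15 with 0 members called (5.6e-04, and 0.063 with an estimated correlation), so it passed only with the preset correlation. Over all genes 0 differed between these lines, with 581 at an unadjusted p under 0.05. Besides KLF2, KLF6 and ZFP36 the rises included IER2 (0.35 ± 0.06, 0.022, lost without several single arrays, at most at 0.18 without Maver-1 sotrastaurin replicate 1), and the falls were RGS1 and RGS2, which were also the 2 falls among the 22 migration and adhesion genes (mean -0.13, adjusted p = 0.0020, and 0.035 with an estimated correlation). Of 15 cholesterol synthesis genes none passed over all genes, and 4 rose adjusted over the list alone, among them HMGCS1 at 0.30 and SQLE at 0.29, with a list mean of 0.11 (adjusted p = 6.8e-04, and 0.035 with an estimated correlation). The cholesterol mean was 0.22 in Z-138 and 0.01 in Maver-1 (0.80), a difference of 0.21 (1.7e-04, and 0.0496 with an estimated correlation, or 0.057 without Jeko-1 DMSO replicate 1). MYC and ribosome biogenesis genes had a mean of 0.10 with 0 of 27 past the threshold (adjusted p = 2.0e-04, and adjusted p = 0.22 with an estimated correlation), with 0.19 in Z-138 and 0.00 in Maver-1, a difference that passed only with the preset correlation (8.5e-07, and 0.15 with an estimated correlation). Housekeeping reference genes moved the same way, with a mean of 0.05 in the insensitive lines (11 of 12 above 0, 0.039, and 0.48 with an estimated correlation) and 0.16 in Z-138. Among 14 germinal centre genes GCSAM fell (-0.72 ± 0.12, 0.017, lost at most at 0.13 without Maver-1 DMSO replicate 2), with a list mean of -0.13 (0.0025, and 0.035 with an estimated correlation). The 28 G2-M genes had a mean of -0.07 with 0 past the threshold (0.0022, and 0.035 with an estimated correlation). Without Jeko-1 DMSO replicate 1 the estimated-correlation adjusted p of each of these lists at 0.035 was 0.056. FOXO target genes had 3 rises (TSC22D3, KLF2 and KLF6) and 1 fall of 23, with a mean of 0.00 and a median of -0.08 (0.38). The fall was of the ubiquitin ligase gene FBXO32 (-0.72 ± 0.13, 0.029), whose call was lost without single arrays, at most at 0.21 without Maver-1 sotrastaurin replicate 1.

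Over the insensitive lines 29 of 12722 genes passed the limma threshold, 14 higher and 15 lower, and 3 changed by at least 1 on the log2 scale. The count was 69 without either Jeko-1 DMSO array, which changes the shared estimate of the spread, 18 without Z-138 sotrastaurin replicate 1, and 13 without Z-138 DMSO replicate 2, Maver-1 DMSO replicate 2 or either Maver-1 sotrastaurin array. With lines as the replicates limma called 1 gene, and with only the 8 arrays compared in the fit 44. Of the genes called in both classes, 7 rose in both (among them KLF2, KLF6, KLF7, RGS19, TSC22D3 and ZFP36, where 0.168 are expected by chance) and 2 fell in both (RGS1 and RGS2, where 0.239 are expected). RGS1 and RGS2 passed as falls in Jeko-1, Z-138 and Maver-1, but not in Mino. The shared rises numbered 11 without Jeko-1 DMSO replicate 1 and 13 without Jeko-1 DMSO replicate 2 (4 and 7 shared falls), and 4 without Jeko-1 sotrastaurin replicate 1, Mino DMSO replicate 1 or Mino sotrastaurin replicate 2.

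**Figure D2:**
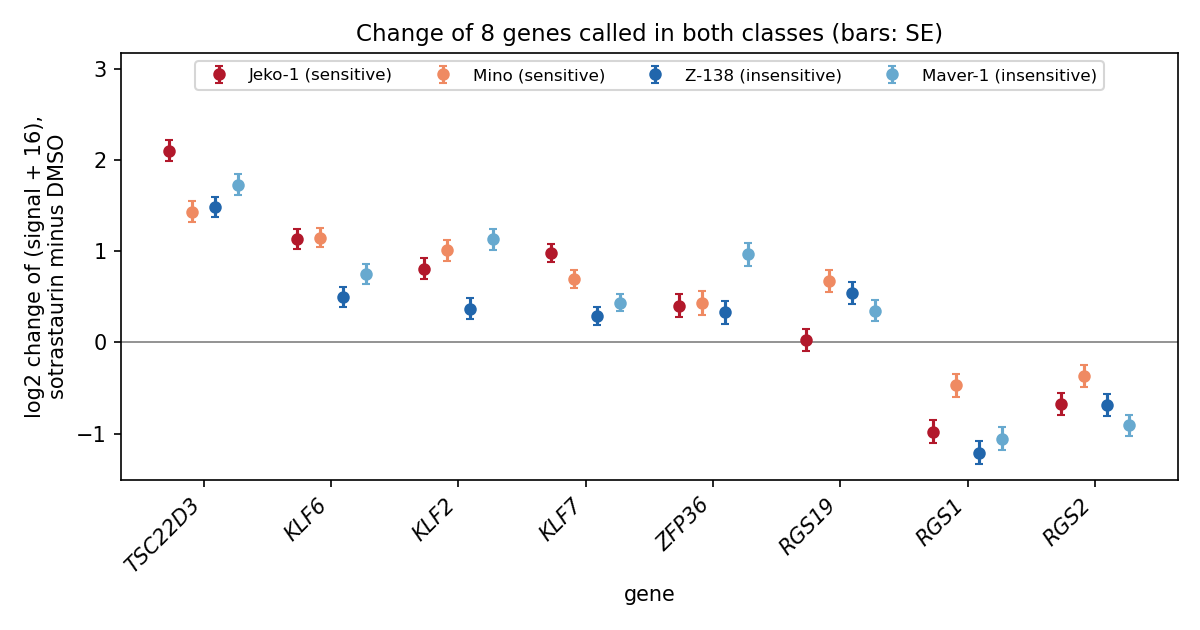
The plot gives the log2 change (± SE from limma, n = 2 arrays per group) of 8 genes called in the same direction in both classes, by line. TSC22D3 lay at 2.10 in Jeko-1, 1.43 in Mino, 1.48 in Z-138 and 1.73 in Maver-1.

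The difference of the responses was tested as an interaction, the change in the sensitive lines minus that in the insensitive lines. NF-kB target genes were among the largest differences. Of those with a signal above 100 in both insensitive lines under DMSO, CD83 differed by -1.50 ± 0.11 (SE, 8 arrays against 8, limma adjusted p = 1.6e-06), TNFAIP3 by -1.32 ± 0.10 (1.6e-06), NFKBIA by -1.32 ± 0.16 (2.7e-04) and NFKB1 by -1.18 ± 0.18 (0.0047). ICAM1 (-1.74 ± 0.14, 4.0e-06) had signals of 236 ± 7.42 and 71.2 ± 3.18 in Z-138 and Maver-1, NFKBID (-2.15 ± 0.15, 6.9e-07) of 21.3 ± 1.56 and 83.7 ± 4.31, and the early transcription factor NR4A3 (-1.44) of 13.2 ± 0.99 and 364 ± 14.6. BCL2A1 (-2.03 ± 0.13), CCL4 (-1.91 ± 0.13), TRAF1 (-1.53 ± 0.22), which encodes an adapter of TNF receptors, EGR3 (-1.48) and the kinase gene MAP3K8 (-1.41 ± 0.17) were near the floor in both insensitive lines, with signals of at most 12.6 under DMSO. They had little room to fall there, so their values do not measure a difference of response. For MAP3K8 the difference came from Mino (-2.53), with 0.07 in Jeko-1 (adjusted p = 0.85), and TRAF1 (-0.37) and EGR3 (-0.39) did not pass in Jeko-1 either. Each of these calls held with any 1 array left out. Of 44 NF-kB targets 21 were lower in this contrast and 0 higher, 30 and 1 adjusted over the list alone, with a mean of -0.67 and 42 of 44 fitted values below 0 (camera adjusted p = 4.0e-33, and 2.4e-04 with an estimated correlation). Over the 21 members with a signal above 100 in both insensitive lines under DMSO the mean was -0.61, with 9 lower, 0 higher and 21 of 21 fitted values below 0 (2.8e-19, and 7.6e-04 with an estimated correlation).

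Genes with a higher change in the sensitive lines included RNF144B (0.98 ± 0.11, 1.4e-04), the proapoptotic HRK (0.80 ± 0.14, 0.011), and FBXO32 (1.06 ± 0.19, 0.010), a target of FOXO factors, which was at 0.73 in Jeko-1 and -0.05 in Mino (0.16 for the difference of these lines). Their calls held with any 1 array left out. Of the genes that rose in both classes, TSC22D3 and KLF2 did not pass the test of a difference: TSC22D3 was at 0.16 ± 0.11 (0.54) and KLF2 at 0.16 (0.56). SPIB was lower in the response of the sensitive lines (-0.70 ± 0.11, 0.0050). Of the FOXO list 3 of 23 were higher, FBXO32, RAG1 and KLF6, and 0 lower, 4 and 0 adjusted over the list alone, with a mean of 0.29 (adjusted p = 1.5e-08, adjusted p = 0.060 with an estimated correlation). The calls of RAG1 (0.80 ± 0.17) and KLF6 (0.52 ± 0.11) were lost without most single arrays, at most at 0.098 and 0.11 without Jeko-1 sotrastaurin replicate 1. Chemokines and cytokines had 4 of 16 lower and 0 higher, 5 and 0 adjusted over the list alone (mean -0.39, adjusted p = 8.3e-07, and 0.0059 with an estimated correlation). Fewer than 3 of these had a signal above 100 in both insensitive lines under DMSO, so the list had little room to fall there. Immediate-early genes had 7 of 30 lower and 2 higher, 12 and 5 adjusted over the list alone (mean -0.27, 9.7e-05, and 0.029 with an estimated correlation), with means of -0.01 in Jeko-1 and -0.34 in Mino. Without the 2 members that also stand in the NF-kB list the mean was -0.21, with 5 lower and 2 higher. Over the 18 of the 30 with a signal above 100 in both insensitive lines the mean was -0.10 and did not pass (0.42). The 28 G2-M genes had a mean of 0.09 with 0 past the threshold (0.020, and 0.078 with an estimated correlation). The unfolded protein list had 2 lower, ATF3 (-0.66 ± 0.12, 0.013) and HERPUD1 (-0.47 ± 0.09, 0.016), and 0 higher of 25, with a mean of -0.20 (9.7e-05, and 0.067 with an estimated correlation). The call of ATF3 was lost at 0.055 without Z-138 DMSO replicate 2, and that of HERPUD1 at 0.055 and 0.054 without replicate 1 of Mino DMSO and of Mino sotrastaurin. With the mean of a gene's probe sets in place of the brightest, the calls of HRK, FBXO32, KLF6, ATF3 and HERPUD1 for the difference were also lost.

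In all, 131 of 12722 genes passed the limma test of the difference, 53 higher and 78 lower. Leaving out single arrays gave counts from 47 (without Z-138 DMSO replicate 2) to 1558 (without Jeko-1 DMSO replicate 2), with 128 without Jeko-1 DMSO replicate 1. Without the latter array the FOXO and unfolded protein lists for the difference had an adjusted p of 0.019 with an estimated correlation (0.060 and 0.067 with all arrays), and the MEK-ERK list one of 0.036 with the preset correlation (0.16 with all arrays), which was 0.17 with an estimated correlation. The counts were 57 and 77 without Jeko-1 sotrastaurin replicates 1 and 2, 55 and 58 without Mino DMSO replicates 1 and 2, 53 and 75 without Mino sotrastaurin replicates 1 and 2, 77 without Z-138 DMSO replicate 1, 79 and 73 without Z-138 sotrastaurin replicates 1 and 2, 59 and 65 without Maver-1 DMSO replicates 1 and 2, and 61 and 51 without Maver-1 sotrastaurin replicates 1 and 2. The test treats arrays as replicates and speaks for these 4 lines: with lines as the replicates limma called 0 genes (798 at an unadjusted p under 0.05).

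Line by line, the fall of NF-kB target genes was larger in Mino than in Jeko-1. The falls in Mino included TRAF1 (-2.90 ± 0.22, SE, 2 arrays against 2, limma adjusted p = 5.9e-07), NFKBID (-2.79 ± 0.15, 1.1e-08), EGR3 (-2.72 ± 0.13, 3.0e-09), BCL2A1 (-2.68 ± 0.13, 3.0e-09) and MAP3K8 (-2.53 ± 0.17, 9.6e-08). There TSC22D3, HBEGF (1.29 ± 0.12), KLF6, PLPP3 (1.08 ± 0.13) and KLF2 rose. Of the NF-kB list 28 of 44 fell in Mino, with a mean of -0.98 (camera adjusted p = 4.0e-64, and 1.9e-05 with an estimated correlation). In Jeko-1 the same list had 12 falls and a mean of -0.35. It passed with the preset correlation but not with an estimated correlation (adjusted p = 0.069). Without Jeko-1 DMSO replicate 1 its mean was -0.30. The difference, Mino minus Jeko-1, was -0.63 over the list with 15 members called lower and 0 higher. In all 125 genes differed between these lines, 65 without Jeko-1 DMSO replicate 1. BCL2A1 (-1.49 ± 0.13, 1.3e-05), CCL4 (-1.36 ± 0.13), ICAM1 (-1.16 ± 0.14) and INHBE (-1.16 ± 0.14) fell in Jeko-1, and TSC22D3 (2.10 ± 0.11, 2.8e-08) rose. TRMT2B (1.63 ± 0.32), EEIG2 (1.43 ± 0.38) and MEX3D (1.36 ± 0.29) also passed in Jeko-1, but not without Jeko-1 DMSO replicate 1 (adjusted p = 0.12, 0.23 and 0.26).

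In Z-138 TSC22D3 (1.48 ± 0.11, 8.9e-06) rose, and RGS1 (-1.21 ± 0.13, 2.4e-04), RNF144B (-0.92 ± 0.11, 6.9e-04) and the histone deacetylase gene HDAC9 (-0.89 ± 0.10, 2.5e-04) fell. In Maver-1 TSC22D3 (1.73 ± 0.11), KLF2 (1.13 ± 0.12) and JUN (1.06 ± 0.13) rose and RGS1 (-1.06 ± 0.13, 0.0011) fell, and JUN was at an adjusted p of 0.055 without Maver-1 sotrastaurin replicate 2. TSC22D3 was among the 2 genes called higher in all 4 lines, and 0 genes were called lower in all 4. Genes whose sotrastaurin arrays lay above both DMSO arrays in every line numbered 47 (23.4 expected from the product of the 4 lines' own shares of such genes), and 38 lay below (20.2 expected). Jeko-1 and Mino shared 10 rises (0.973 expected) and 23 falls (6.07 expected), the latter including CD86, NFKB1 and RELB. These counts depend on single arrays, with 6 rises and 11 falls without Jeko-1 DMSO replicate 1, 36 and 65 without Jeko-1 DMSO replicate 2, 5 and 7 without Jeko-1 sotrastaurin replicate 1, and 5 and 16 without Jeko-1 sotrastaurin replicate 2. Without Mino DMSO replicates 1 and 2 there were 6 and 7 rises and 14 and 13 falls, without Mino sotrastaurin replicates 1 and 2 there were 7 and 8 rises and 14 falls each, and without Maver-1 sotrastaurin replicates 1 and 2 there were 6 rises each and 16 and 15 falls. The log2 changes of these lines had r = 0.113 across genes, which are not independent replicates.

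The number of genes past the limma threshold was 794 in Jeko-1 (302 higher), 198 in Mino (41 higher), 17 in Z-138 (4 higher) and 17 in Maver-1 (10 higher). Without Jeko-1 DMSO replicate 1 the counts were 30, 333, 24 and 26, and without Jeko-1 DMSO replicate 2 Jeko-1 had 3491, Mino 331 and Maver-1 26. Of the other arrays of each line, Jeko-1 sotrastaurin replicate 1 left 18 in Jeko-1, Mino DMSO replicate 1 and Mino sotrastaurin replicate 1 left 93 and 122 in Mino, Z-138 DMSO replicates 1 and 2 and Z-138 sotrastaurin replicates 1 and 2 left 5, 6, 6 and 69 in Z-138, and Maver-1 sotrastaurin replicates 1 and 2 and Maver-1 DMSO replicate 2 left 8, 6 and 7 in Maver-1. Arrays of other lines moved the count in Jeko-1 through the shared spread, to 511 and 502 without Mino DMSO replicates 1 and 2, 528 and 522 without Mino sotrastaurin replicates 1 and 2, 472 and 474 without Z-138 DMSO replicates 1 and 2, 433 and 435 without Maver-1 DMSO replicates 1 and 2, and 433 and 357 without Maver-1 sotrastaurin replicates 1 and 2.

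**Figure D3:**
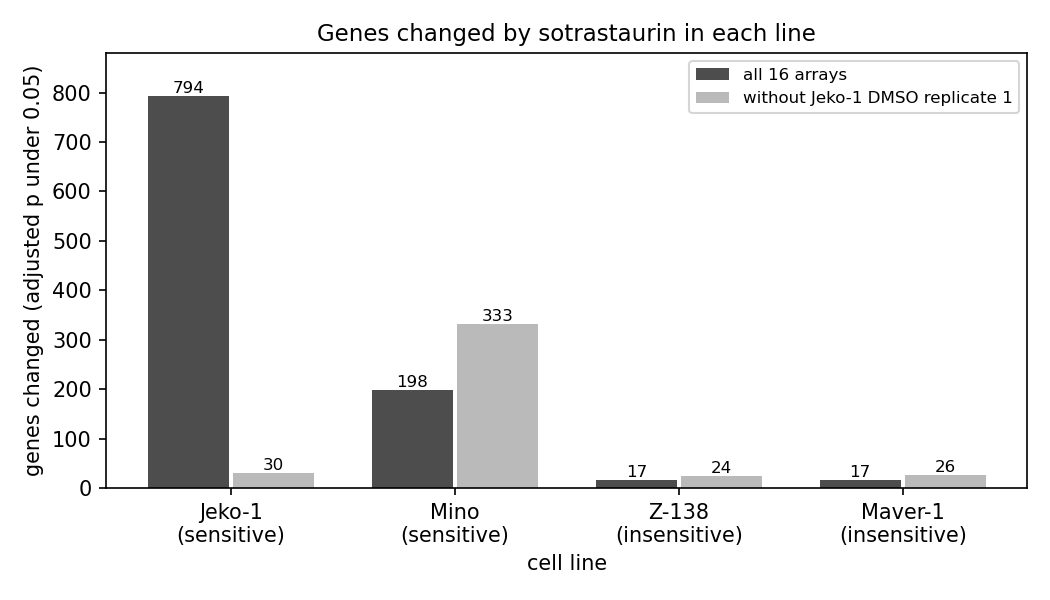
Bars give the number of genes past the limma threshold in each line with all 16 arrays and without Jeko-1 DMSO replicate 1. Jeko-1 went from 794 to 30 genes and Mino from 198 to 333.

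Under DMSO the sensitive lines were compared with the insensitive lines, 2 lines against 2, with each line's arrays averaged. No gene passed the limma threshold (648 at an unadjusted p under 0.05, smallest adjusted p = 0.42), so the following genes are given as values. They are from those with the smallest p, except PRKCB, which belongs to the fixed set of always-named genes. CDKN2A, which encodes the cell-cycle inhibitor p16, had a signal of 566 ± 9.33 in Jeko-1 and 945 ± 12.6 in Mino against 5.25 ± 0.64 in Z-138 and 0.55 ± 0.35 in Maver-1 (SD, n = 2), a log2 difference of 5.32 ± 0.48. PRSS21, which encodes a serine protease, differed by 4.86 ± 0.42 and TNFSF8, which encodes the CD30 ligand, by 3.42 ± 0.42. Signals of these 3 genes were near the floor in the insensitive lines, so the size of these differences depends on the added 16. HBEGF was at 77.3 ± 11.5 and 41.5 ± 4.31 in the sensitive lines against 1398 ± 92.6 and 1260 ± 67.2 in Z-138 and Maver-1 (-4.20 ± 0.43). RGS1 was at 37.2 ± 3.25 and 29.5 ± 0.21 against 626 ± 64.8 and 443 ± 20.9 (-3.46 ± 0.44). PRKCB, which encodes a protein kinase C isoform of B-cell receptor signalling, had 1958 ± 180 in Jeko-1 and 1558 ± 52.8 in Mino against 125 ± 15.7 in Z-138 and 460 ± 5.30 in Maver-1 (2.77 ± 0.63, adjusted p = 0.82).

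Among the lists under DMSO, NF-kB targets had a class difference of 0.73 (camera adjusted p = 0.014) and chemokines and cytokines of 0.91 (0.017), with 0 members called in either, and unfolded protein genes were lower in the sensitive lines (mean -0.58, adjusted p = 2.0e-04). None of these held with an estimated correlation (adjusted p = 0.85 for each). The NF-kB difference came with a level in Mino apart from the other lines: the mean log2 level of the 44 genes under DMSO was 8.56 in Mino, 6.78 in Jeko-1, 6.93 in Z-138 and 6.95 in Maver-1. Under sotrastaurin it was 7.58, 6.43, 6.92 and 6.97 in the same order.

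**Figure D4:**
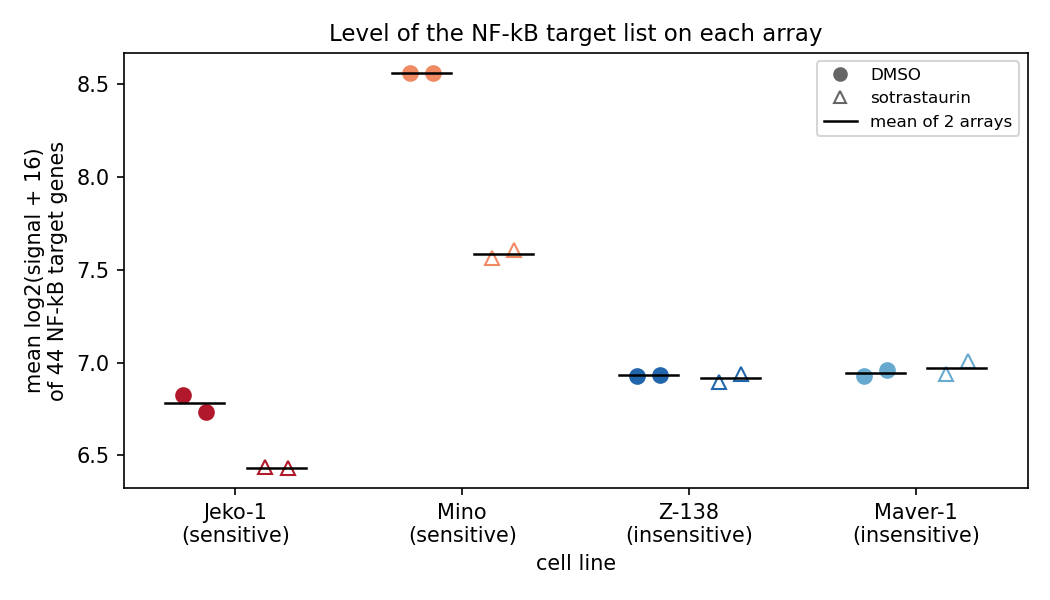
Points give the mean log2 level (log2 of signal plus 16) of the 44 NF-kB target genes on each of the 16 arrays, by line and agent. The Mino arrays lay near 8.56 under DMSO and 7.58 under sotrastaurin, and the Z-138 arrays near 6.93 and 6.92.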

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

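Tests of the array that stands apart, of the starting level in the insensitive lines, of serum, of Mino alone, of that array as the source of the larger fall in Mino, array weights, the count of splits balanced by line, the tests of lists between the lines of a class and the lists of genes with a signal above 100 in both insensitive lines were chosen only after the result was seen. The results here were picked because a limma or camera test of the difference between classes or lines was passed, or because a signal appeared in probe sets outside the comparisons. Groups of 2 arrays are too small for a test of single outlying arrays.

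The response of NF-kB target genes differed between the classes by -0.67 on the log2 scale, a fall in Mino and in Jeko-1 (in the latter not past the threshold with an estimated correlation, adjusted p = 0.069) and none past the threshold in Z-138 and Maver-1. The tables argue against a starting level too low to fall, because 12 NF-kB genes with at least as high a mean log2 level in the insensitive lines and a signal above 100 there differed by -0.51 on average (SE over genes 0.135, 12 of 12 below 0), and the 9 of these that were also at least as high in mean signal by -0.65 (SE 0.153). The 12 ranged from -1.32 for TNFAIP3 to values near 0 for MARCKS (-0.003), IRF1 (-0.01) and TNFAIP8 (-0.02). The tables also argue against a response of Mino alone. Jeko-1 minus the insensitive lines was -0.35 (SE over genes 0.0717, 36 of 44 below 0), and -0.31 without Jeko-1 DMSO replicate 1. With all arrays that difference had an unadjusted camera p of 8.5e-07, and 0.0041 with an estimated correlation. Each SE over genes, here and below, treats genes that move together as independent. It does not measure the spread between cultures or lines. Serum content cannot be told apart from class, since 0 sensitive lines were grown in the serum content of the insensitive lines. Within each line the DMSO and sotrastaurin arrays shared the serum content, so the fall within Mino or Jeko-1 does not compare serum contents. Whether that fall depends on the serum content cannot be told, since no line was grown in both contents. A dependence of NF-kB on protein kinase C in the sensitive lines stays a hypothesis, since sotrastaurin was the only agent compared with DMSO.

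The number of genes called in Jeko-1, 794, was above the 198 in Mino, which a broader response or the single Jeko-1 DMSO array that stands apart could give. With all arrays kept the ranking turned in other fits, with 2 genes in Jeko-1 and 170 in Mino from only the arrays compared, and 21 and 374 with array weights. Over the genes called in Jeko-1 the median size of the change against DMSO replicate 2 alone was 0.368, against 0.749 for DMSO replicate 1 alone, a ratio of 0.491 where the other lines had 0.896 to 0.968, but these genes were called with that array, so part of the ratio is built in and it excludes nothing. Without Jeko-1 DMSO replicate 1 Jeko-1 had 30 called genes and Mino 333, but without Jeko-1 sotrastaurin replicate 1, which did not stand apart, they had 18 and 184, so the drop is not specific to the DMSO array (3491 and 533 in Jeko-1 without DMSO replicate 2 and sotrastaurin replicate 2). The count of 794 used a spread shared by all 8 groups. The Jeko-1 DMSO pair differed by more than the other pairs (SD of the log2 difference 0.325, against 0.178 to 0.226). With only the arrays compared and with array weights Jeko-1 fell below Mino, so the count is no evidence of a broader response in Jeko-1. How far the array that stands apart is the source of the count cannot be told.

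Between Mino and Jeko-1, 125 genes differed in their change (65 without Jeko-1 DMSO replicate 1), and the NF-kB list differed by -0.63. The tables argue against signals near the floor in Jeko-1, since 20 NF-kB genes with a signal above 100 in both lines differed by -0.51 (SE over genes 0.0995, 17 of 20 below 0), and against the array that stands apart, since the mean was -0.68 without it. A lower starting level in Jeko-1 cannot be told apart from the line, because only 1 NF-kB gene was at least as high there with a signal above 100 in both, at -0.18. That the lines differ in how far NF-kB is driven by protein kinase C is a hypothesis, and it was not tested.

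Chance splits bear on the counts. Within the sensitive lines 19 genes passed in a fit with line as a term, and the highest of the other 33 splits that could be fitted had 0 with limma, so 1 of 34 splits gave as many. That share is under 0.05 only because splits that are not balanced by line are counted. The 18 balanced ones are too few for a share under 0.05 (real 19, highest other 0, 1 of 18). At an unadjusted p under 0.05 the real split had 1488 and the highest other 2012, and 4 of 34 splits gave as many. The other splits as large (1676, 1907 and 2012) each set Jeko-1 DMSO replicate 1 alone against the other Jeko-1 arrays, so they carry that array's distance. Of the 18 balanced splits the real one had the most, with 1244 in the next. Since 18 are too few for a share under 0.05, that count does not exclude chance. Within the insensitive lines the real split had 21 genes and the highest other 0, again 1 of 34, and the 18 balanced by line are too few for a share under 0.05 here as well (highest other 0). The unadjusted count does not exclude chance (1043 in the real split, 1837 in the highest other, 6 of 34 as large). For the 131 genes that differed between classes the 3 splits of the 4 lines are too few for a share under 0.05 (highest other 30, so 1 of 3 gave as many, and 1816 against 1879 unadjusted), and for the class comparison under DMSO they are also too few, with 0 in the real split (648 unadjusted) and 0 in the highest other (537 unadjusted), so 3 of 3 gave as many. The count of 131 ranged from 47 without Z-138 DMSO replicate 2 to 1558 without Jeko-1 DMSO replicate 2 when single arrays were left out.

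Immediate-early genes differed between classes by -0.27 on average, with means of -0.01 in Jeko-1, -0.34 in Mino, 0.02 in Z-138 and 0.17 in Maver-1, and the difference of Z-138 and Maver-1 did not pass with an estimated correlation (adjusted p = 0.063). Over the 18 immediate-early genes with a signal above 100 in both insensitive lines the class difference was -0.10 and did not pass (0.42). Chemokines and cytokines differed by -0.39 between classes, with fewer than 3 members above that signal. This list passed in Mino (-0.48) and not in Jeko-1 (-0.21, adjusted p = 0.25), and Mino minus Jeko-1 was -0.27 (0.0025, and 0.030 with an estimated correlation). FBXO32 differed by 1.06, with 0.73 in Jeko-1 and -0.05 in Mino, and fell in the insensitive lines. The call of that fall was lost without single arrays. The call of the difference was lost with the mean of a gene's probe sets in place of the brightest. RNF144B differed by 0.98 between classes, by 1.39 between Mino (0.47) and Z-138 (-0.92), and by 1.08 between Mino and Maver-1 (-0.61). In Jeko-1, the other sensitive line, RNF144B did not pass the threshold. RAG1 differed by 1.48 ± 0.233 between Jeko-1 (0.58) and Maver-1 (-0.90), but its value in Jeko-1 was 0.29 (adjusted p = 0.51) without Jeko-1 DMSO replicate 1. JUN differed by -1.73 between Mino (-0.67) and Maver-1 (1.06). Of 6253 kept probe sets without a single gene name, which no comparison used, limma called 32 in the sensitive lines, 3 in the insensitive lines and 5 for the difference between classes.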

How the results depend on the processing

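Array weights, the filter at a signal of 100 and the class difference over sotrastaurin arrays were chosen only after the result was seen. Over the other alternatives and these, the NF-kB list kept its side of the threshold in 88 of 89 settings by comparison, with camera at the preset correlation. The estimated correlation is not part of this tally. With it and all arrays the list did not pass in Jeko-1 or for the class difference under DMSO, as given above. Its mean near 0 changed sign in the insensitive lines with a filter on the mean of 16 arrays (0.0068 to -0.00084), and in Z-138 with quantile normalization (-0.014 to 0.0038) and median centring (0.0058). Of the settings for named genes 4582 stayed on their side, 469 lost and 34 gained a call, and 1 reversed (SETMAR, sotrastaurin effect in Jeko-1, -0.45 in all arrays and 0.089 at an adjusted p of 0.73 without probe sets marked as binding several genes). Of the counts 97 stayed within 1.5 times and 32 did not. These totals leave aside settings without single arrays. The cause was not tested.

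Leaving out single arrays gave 139 to 2593 genes in the sensitive lines (NF-kB list -0.69 to -0.64), 13 to 69 in the insensitive (-0.01 to 0.02), 47 to 1558 for the difference (-0.69 to -0.64), 18 to 3491 in Jeko-1 (-0.40 to -0.30), 93 to 333 in Mino (-1.0 to -0.96), 5 to 69 in Z-138 (-0.04 to 0.01), 6 to 26 in Maver-1 (-0.01 to 0.06), and 0 to 0 under DMSO (0.71 to 0.76).

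A pseudocount of 1 gave 84 genes for the difference. No filter gave 77 for the difference and 174 in Jeko-1. The mean of a gene's probe sets gave 51 in the insensitive lines, and every probe set tested gave 580 in the sensitive lines, 1423 in Jeko-1, 340 in Mino and 26 in Maver-1. Without a variance trend Jeko-1 had 517. A minimum log2 change of 1 left 19 sensitive, 3 insensitive, 24 difference, 28 Jeko-1, 59 Mino, 4 Z-138 and 6 Maver-1 genes. Only the arrays compared in the fit gave 120 sensitive, 44 insensitive, 2 Jeko-1 and 4 Z-138 genes. A block for line by replicate number gave 17 insensitive, 81 difference and 438 Jeko-1 genes, although deviations of equally numbered arrays correlated across genes at -0.110 in Jeko-1, 0.0850 in Maver-1, 0.205 in Mino and 0.228 in Z-138, so the numbers were not taken as pairs, which stays undecided in Mino and Z-138. With lines as replicates limma called 14 sensitive, 1 insensitive and 0 difference genes (798 at an unadjusted p under 0.05), and with arrays as replicates 7864 under DMSO. The filter at a signal of 100 gave 1 gene under DMSO. Array weights gave 80 insensitive, 21 Jeko-1, 374 Mino and 34 Maver-1 genes. The NF-kB class difference was 0.062 over the sotrastaurin arrays (adjusted p = 0.71, and 0.73 over the DMSO arrays). Signals near the floor limit folds for BCL2A1 and CCL4 in the insensitive lines.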

Other observations

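The test of the class difference over the sotrastaurin arrays was chosen only after the result was seen, and the genes given by their DMSO levels were chosen after their values were seen.

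TRAF3, which encodes a negative regulator of the alternative NF-kB pathway, was near the floor in Maver-1 under DMSO with a signal of 0.30 ± 0.14 (SD, n = 2), against 315 ± 104 in Z-138, 358 ± 80.6 in Jeko-1 and 374 ± 27.7 in Mino. PRKCA, a conventional protein kinase C isoform, was at 3.90 ± 1.13 in Mino and at 255 ± 5.02 to 550 ± 28.6 in the other lines. CCND2, a D-type cyclin gene, was at 1238 ± 42.9 in Mino and at most 37.0 ± 16.5 elsewhere, and CD5, a surface marker of mantle cell lymphoma, was at 241 ± 1.34 in Mino and 1.30 ± 0.42 in Z-138.

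Of 17 plasma cell genes 2 fell in the sensitive lines, ELL2 (-0.61 ± 0.09, limma adjusted p = 0.0013) and SLAMF7 (-0.46 ± 0.08, 0.0046), and the list did not pass (mean -0.12, camera adjusted p = 0.060, and 0.17 with an estimated correlation, or 0.032 and 0.20 without Jeko-1 DMSO replicate 1). SLAMF7 fell in Mino (-0.77) and did not pass in Jeko-1 (-0.16). IRF4, a transcription factor of activated B cells, fell in Mino (-0.89 ± 0.12, 2.8e-04), from 2149 ± 80.4 to 1148 ± 3.18, and went from 857 ± 210 to 1127 ± 11.3 in Jeko-1 (0.41 ± 0.12, 0.0504). IFIH1, an RNA sensor gene, was the fall among 25 type I interferon genes in the sensitive lines (-0.66 ± 0.08, 7.7e-05), with -0.99 in Mino and -0.33 in Jeko-1 (0.072). The transferrin receptor gene TFRC fell there by 0.29 ± 0.05 (0.0034), with -0.39 in Mino and -0.18 in Jeko-1 (0.11). CD69, an early activation antigen, fell by 0.80 ± 0.12 (0.0016), with -1.10 in Jeko-1 and -0.50 in Mino (0.25). In Z-138 cholesterol synthesis genes had a mean of 0.22 (adjusted p = 3.6e-06, and 0.016 with an estimated correlation), and in Maver-1 of 0.01. Housekeeping reference genes were also higher in Z-138 (0.16, 9.0e-05, and 0.21 with an estimated correlation). With quantile normalization their mean was 0.02 (0.94) and that of the cholesterol list 0.22 (1.9e-06).

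Under DMSO the mean log2 level of NF-kB targets was higher over the sensitive lines through Mino (8.56). Jeko-1 (6.78) lay below Z-138 (6.93) and Maver-1 (6.95). Whether the higher level in Mino depends on protein kinase C was left open. The class difference was 0.73 over the DMSO arrays and 0.062 over the sotrastaurin arrays, but the latter is the former plus the difference of the responses (-0.67) and adds no evidence. It also averages lines that lay apart, since under sotrastaurin Mino stayed at a mean log2 level of 7.58, above Z-138 at 6.92 and Maver-1 at 6.97, and Jeko-1 lay at 6.43. The DMSO difference rests on Mino, and with 2 lines per class it did not hold with an estimated correlation (adjusted p = 0.85).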
